A study of Mus musculus with 20 samples.

How the data were processed

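Total RNA of 20 HCC1954 xenografts was hybridised to NanoString nCounter oligonucleotide probes, per the labels' protocols, and 770 mouse genes were measured in each tumour. The 4 treatment groups and the replicate numbers were taken from the labels, with 5 mice per group. Mice were assigned at random by tumour size before treatment, per the labels' protocols, so replicates are separate animals.

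The deposited values are a normalized signal on a linear scale, rounded to 2 decimals by the authors; software and scaling steps are not given in the sources used here. The steps between low values showed that each tumour's signal was its barcode counts times 1 factor. Dividing by that factor gave whole counts, within 0.1 count, for 100% of the 15359 values above the floor of the deposited table; the other 41 of 15400 values stood at that floor of 1.00. The factors ranged from 0.647 to 1.40 and set the geometric mean of 20 reference genes to 355.74 to 355.75 in every tumour. Mean differences of those reference genes between tumours were therefore fixed by the authors' scaling. The recovered totals were 359848 to 699060 counts per tumour. Factors were 1.06 to 1.40 in the trastuzumab conjugate group, 0.647 to 1.19 with trastuzumab, 0.683 to 1.07 with the rituximab conjugate and 1.09 to 1.27 with rituximab. The limit of 3 counts, 1.94 to 4.21 on the normalized scale, covers counting error only. Each of the 40 pairs of tumours within groups differed by more than counting noise, with chi-square per degree of freedom of 6.97 to 61.2, so no pair was merged into 1 sample; a repeat run of the same RNA could exceed counting noise too and is not excluded by this.

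Of the gene names, 754 were current symbols, 8 were updated through a table of gene names, and 8 kept the name of the file. Gpr44 and Ptgdr2 are names of the same gene. Members of families of near-identical genes (Klra, H2 and Ifna genes) may share probe signal, and binding of human tumour RNA to the mouse probes was not tested.

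Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3: lmFit and eBayes with default settings, all 20 tumours in 1 fit of 4 group means with 16 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over 770 genes and a threshold of 0.05. The contrasts were the trastuzumab conjugate against trastuzumab, the rituximab conjugate against rituximab, the conjugates against each other, the antibodies against each other, and the interaction. Gene lists were tested with limma's fry (directional p), adjusted over 30 of the 34 lists fixed in advance; the others were the key genes and 3 lists with fewer than 3 measured members. A total of 368 measured genes were in a list. Fry asks whether the members move, on balance, in 1 direction, and does not compare a list with other genes; camera, with a preset correlation of 0.01 and with an estimated correlation, does. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each contrast, the 8 largest changes in each direction among genes that passed (or every gene where 10 or fewer passed), up to 4 members of each list with the lowest p, members that passed against their list's direction, and a list of 31 key genes. Isg15, Itgam, Spn, Il4ra, Ctsl and genes named for the tumours that stood apart were chosen after their values were seen. Values of some genes that the rule names are not reported here.

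Alternatives were other scalings (median centring, reference genes, quantile), the lowest 25% of genes left out, a pseudocount of 10, eBayes with trend and robust settings, array weights, the compared groups alone, the replicate number as a block, camera, and each tumour left out in turn. Added after seeing the data were edgeR 4.0.16 quasi-likelihood tests on the recovered counts, with the authors' factors or with TMM, the removal of both tumours that stood apart, and the removal of Cd3eap from the T cell list. A planned filter on negative controls was not run, since negative controls were not used here.

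The scripts were tested on simulated counts with the means and depths of these tumours and 200 changed genes. For the trastuzumab conjugate against trastuzumab, 61 of 66 genes changed 4-fold, 54 of 67 changed 2-fold and 43 of 67 changed 1.5-fold were recovered, with 6 false calls among 570 unchanged genes. For the interaction these were 61 of 66, 43 of 67 and 14 of 67, with 2 false calls. False calls were 12 for the rituximab conjugate against rituximab and 11 for the antibodies against each other. With 5 of 30 lists raised 1.5-fold, fry recovered 5 and 4 for the trastuzumab conjugate against trastuzumab and the interaction, and with no change it passed 0. Simulated genes were drawn independently, whereas the estimated correlation within lists of these data reached 0.575. The simulation therefore does not measure false passes of fry in these data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.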

Results

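Mouse transcripts were counted in 20 tumours of HCC1954, a human breast cancer cell line with amplified HER2, grown under the skin of SCID/beige mice. These mice lack mature T and B cells and have impaired natural killer (NK) cells. Groups of 5 mice each had received 5 mg/kg of an antibody into the abdominal cavity 1 day earlier: trastuzumab or rituximab, each given either plain or as a T785-ISAC. Trastuzumab binds HER2 on the tumour cells, whereas rituximab binds CD20, a B cell protein. An immune-stimulating antibody conjugate (ISAC) is an antibody carrying an agonist of innate immune receptors, here T785, an agonist of Tlr7 and Tlr8. The 2 ISACs are called the trastuzumab conjugate and the rituximab conjugate below. The nCounter assay, which counts barcoded probes bound to RNA without amplification, covered 770 mouse genes, mostly of the immune system. Recovered totals ranged from 359848 to 699060 counts per tumour, and 3 counts, the limit that a count of 0 allows, corresponded to normalized values of 1.94 to 4.21. Levels are given as normalized counts, mean ± SD (n = 5), and changes as log2 fold changes of the value + 1, which understate the change of low genes.

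The first comparison asked what the conjugated agonist adds to the antibody that binds the tumour. After the trastuzumab conjugate, 79 genes differed from trastuzumab, 76 higher and 3 lower. The largest changes were in chemokines. Cxcl11, a ligand of the chemokine receptor Cxcr3, stood at 423 ± 73.7 (SD, n = 5) against 41.4 ± 15.1, a change of 3.40 (95% interval 2.45 to 4.35, adjusted p = 4.33e-05). Cxcl9, another Cxcr3 ligand, rose from 61.1 ± 13.7 to 529 ± 153 (SD, n = 5; 3.09, adjusted p = 4.64e-06). Ccl4, which attracts monocytes, rose from 27.2 ± 9.51 to 231 ± 74.0 (SD, n = 5; 3.04, adjusted p = 2.00e-06). The 5 values of each group did not overlap for 97 of the 770 genes, where chance gives 0.794% or 6.1, and 64 of these were among the 79.

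Of 11 measured chemokines that attract monocytes, 7 rose and none fell (9 higher when adjusted over the list alone). They included Ccl5 (1.93), Ccl3 (1.89), Ccl12 (1.20), Ccl2 (1.19) and Ccl7 (0.97). The list median was 0.97, with an adjusted p = 9.57e-06 by fry and an adjusted p = 0.205 by camera with an estimated correlation. Here and below, an adjusted p with an estimated correlation is from camera, which compares the list with the other genes of the panel. Among 12 chemokines that attract lymphocytes, Cxcl9, Cxcl11 and Ccl5 rose and Ccl17 fell (7 higher and 1 lower when adjusted over the list alone; median 1.18, adjusted p = 0.000674, and adjusted p = 0.406 with an estimated correlation). The call of Ccl17 was lost with a pseudocount of 10 (adjusted p = 0.0936 by limma). It was also lost by edgeR, with the authors' factors (adjusted p = 0.0754) or with TMM (0.0547). Cxcl10, the other interferon-induced ligand of Cxcr3, did not pass (1.29, adjusted p = 0.0702), although it did without the lowest 25% of genes, with a pseudocount of 10, with trend and robust settings, with array weights and with the compared groups alone (adjusted p of 0.0493 to 0.0134).

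Of 13 genes of Fc receptors and their signalling, which bind the constant part of antibodies, 8 rose (9 when adjusted over the list alone). Fcgr4, an activating receptor of myeloid cells, rose from 357 ± 46.0 to 1188 ± 254 (SD, n = 5; 1.71, adjusted p = 2.09e-06). Fcgr1 (0.97), the inhibitory receptor Fcgr2b (0.70) and the Src family kinase Lyn (0.59) also rose. The list median was 0.59 (adjusted p = 0.000363, and adjusted p = 0.35 with an estimated correlation). Of 17 genes of the interferon gamma response and MHC class I presentation, 9 rose (11 when adjusted over the list alone). Examples are the guanylate-binding proteins Gbp5 (1.43) and Gbp2b (1.15) and the immunoproteasome subunit Psmb8 (0.68); the list had a median of 0.54 (adjusted p = 0.000568, and adjusted p = 0.35 with an estimated correlation). Of 30 interferon-stimulated genes, 7 rose, among them Ifitm1 (1.01), Irf7 (0.88) and Zbp1 (0.83), and 10 when adjusted over the list alone (median 0.48, adjusted p = 0.0294, and adjusted p = 0.512 with an estimated correlation).

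Among 17 proinflammatory cytokines and their antagonists, Il1rn, Il12b, Tnf and Il1a rose (4 also when adjusted over the list alone; median 0.20, adjusted p = 0.0121, and adjusted p = 0.547 with an estimated correlation). The largest change was in Il1rn, which codes for the interleukin 1 receptor antagonist: 2267 ± 871 against 588 ± 260 (SD, n = 5; 2.09, adjusted p = 0.0016). Il12b (1.01), a subunit of interleukins 12 and 23, and Tnf (0.99) had levels of 65.4 ± 19.2 and 35.4 ± 7.41 after the conjugate (SD, n = 5). Il6 (0.20, adjusted p = 0.597) and Il1b (0.61, adjusted p = 0.328) did not pass. In the list of alternative activation, the anti-inflammatory cytokine Il10 rose from 12.4 ± 3.48 to 77.01 ± 30.03 (SD, n = 5; 2.48, adjusted p = 4.00e-05) and Il4ra rose, whereas Ccl17, near the limit of 3 counts, fell. The fall of Ccl17 did not pass with a pseudocount of 10 or with edgeR. That list had a median of 0.05 over 12 members (3 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0226, and adjusted p = 0.861 with an estimated correlation). Its median was below 0 under both other scalings, with an adjusted p = 0.475 and 0.421.

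Genes of cytotoxic granules rose as well: Gzmb from 14.4 ± 6.01 to 54.2 ± 7.61 (SD, n = 5; 1.93, adjusted p = 0.000187), Prf1 by 1.52 and Gzma by 1.43. These and Klra2 were the 4 of 22 NK and cytotoxic cell markers that passed (8 when adjusted over the list alone; median 0.38, adjusted p = 0.0067, and adjusted p = 0.512 with an estimated correlation). The NK receptor Ncr1 did not pass (57.5 ± 7.24 against 66.2 ± 11.4, SD, n = 5; adjusted p = 0.558). Of 16 genes of antigen presenting cell activation, 5 rose, including the costimulatory receptor Cd40 (0.91), the homing receptor Ccr7 (0.91) and the checkpoint ligand Cd274 (1.27), and 6 when adjusted over the list alone (adjusted p = 0.00115, and adjusted p = 0.436 with an estimated correlation). Of 12 NF-kB pathway genes, 5 rose (7 when adjusted over the list alone), among them Icam1 (0.72), Nfkbia (0.61) and Rel (0.43), with an adjusted p = 0.00012, and adjusted p = 0.35 with an estimated correlation. The adaptor of toll-like receptors Myd88 rose by 0.55. Tlr7 (-0.43, adjusted p = 0.27) and Tlr8 (0.31, adjusted p = 0.206), the receptors of the agonist, did not pass.

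The 3 lower genes were Cx3cr1, Cd33 and Ccl17. Cx3cr1, the receptor of the chemokine fractalkine on monocytes and macrophages, stood at 82.4 ± 9.05 against 294 ± 64.7 (SD, n = 5), a change of -1.80 (95% interval -2.18 to -1.42, adjusted p = 2.09e-06). Its levels in the rituximab conjugate and rituximab groups were 348 ± 97.8 and 286 ± 46.2 (SD, n = 5). Cd33, a sialic acid-binding receptor of myeloid cells, changed by -1.01 (adjusted p = 9.78e-05). Ccl17, at 2.47 ± 1.71 against 7.39 ± 1.70 (SD, n = 5), lay near the limit of 3 counts (-1.39, adjusted p = 0.0196). With a pseudocount of 10 its change was -0.485 and did not pass (adjusted p = 0.0936 by limma). Nor did Ccl17 pass by edgeR, with the authors' factors (adjusted p = 0.0754) or with TMM (0.0547). Its call was also lost in at least 1 fit that left out a tumour. Among 8 monocyte markers, Fcgr4, Itgam and Spn rose beside the fall of Cx3cr1 (4 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0226, and adjusted p = 0.656 with an estimated correlation). Of 14 macrophage markers, 2 rose, Fcgr1 and the scavenger receptor Msr1 (0.62), and the macrophage marker Emr1, now called Adgre1, did not pass (0.04, adjusted p = 0.909).

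**Figure D1:**
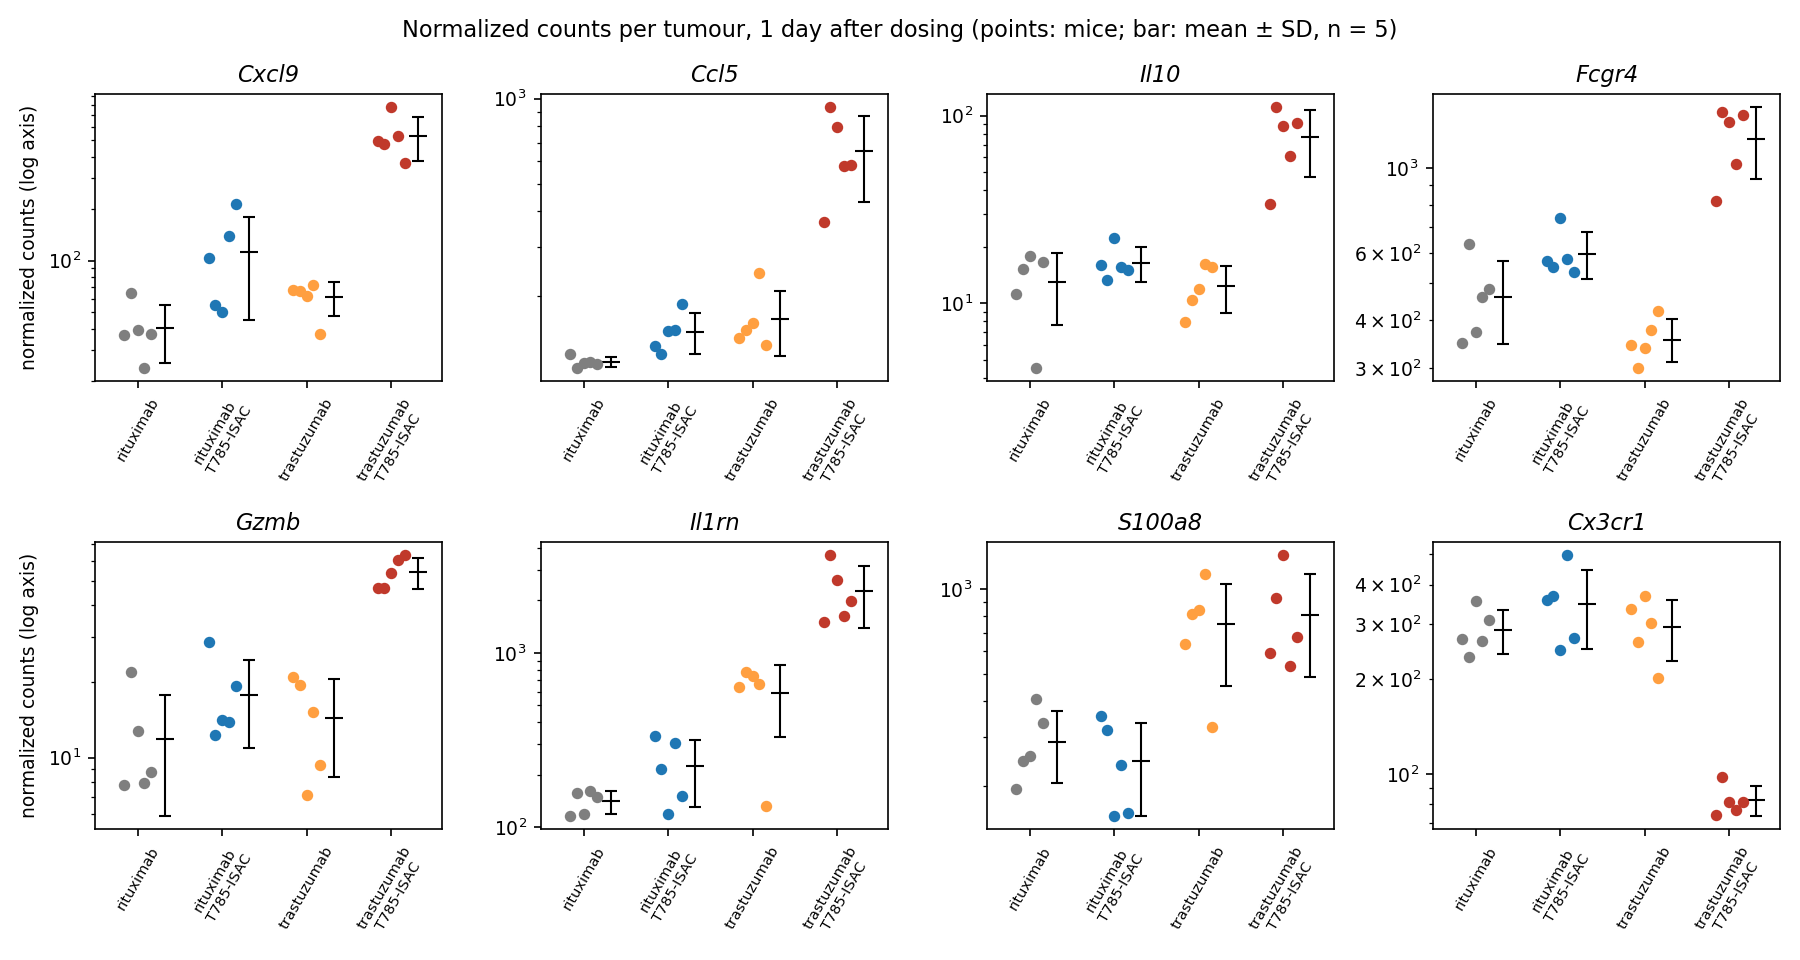
Normalized counts (log axes) of 8 genes in each of the 20 tumours, by treatment; points are mice, bars are mean ± SD (n = 5). Cxcl9, Il10, Fcgr4 and Gzmb are higher in the 5 trastuzumab conjugate tumours than in any other tumour, and Cx3cr1 is lower, at 82.4 ± 9.05.

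Of 30 gene lists, 14 passed fry, each upwards (4 upwards and 6 downwards with median centring, 7 and 5 with quantile normalization); limma's moderated test gave the gene calls. With a correlation estimated from the data, 0 of the 30 lists passed camera. With the preset correlation 10 did, 7 upwards and 3 downwards: MHC class II (adjusted p = 0.0116), endothelial markers (adjusted p = 0.0116) and fibroblast and matrix genes (adjusted p = 0.0273). The balance of calls depended on scaling: centring each tumour on its median gave 77 genes (46 higher, 31 lower) and quantile normalization 77 (40 higher, 37 lower). These scalings moved the median change of all genes by -0.185 and -0.165, and 43 genes (40 higher, 3 lower) and 4 lists, both chemokine lists just described, Fc receptors and interferon gamma with MHC class I, passed in the same direction under all 3 scalings. Of the genes named as changed here, Fcgr2b, Irf7, Il1a, Rel, Nfkbia, Spn and Il4ra passed under neither other scaling, and Ccr7, Klra2, Myd88 and Itgam not under quantile normalization.

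The next comparison asked whether the conjugate changes expression when its antibody has no target on the tumour cells. After the rituximab conjugate, 7 genes were higher than after rituximab and 0 were lower. Tnf stood at 26.3 ± 4.18 against 10.4 ± 2.20 (SD, n = 5; 1.27, 95% interval 0.81 to 1.73, adjusted p = 0.00638). The chemokines Cxcl11 (1.96, adjusted p = 0.0447), Ccl4 (1.52, adjusted p = 0.0113) and Ccl12 (0.69, adjusted p = 0.0447) rose, as did Gbp5 (1.17, adjusted p = 0.0151), the immunoproteasome subunit Psmb10 (0.64, adjusted p = 0.0447) and Tnfrsf11a, the receptor of the osteoclast factor RANKL (0.60, adjusted p = 0.00638). The groups did not overlap for 16 of the 770 genes, where chance gives 6.1, and these included the 7 genes except Cxcl11, Gbp5 and Psmb10. All 7 were also higher after the trastuzumab conjugate, where independent lists would share 0.72 genes. These comparisons share no tumours, but they share each gene's estimate of spread from the same fit. A gene of low spread is favoured in both, so the lists are not independent.

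Other genes with positive values did not pass: Cxcl9 (1.32, adjusted p = 0.0688), Cxcl10 (1.58, adjusted p = 0.094), Fcgr1 (0.57, adjusted p = 0.0688), Irf7 (0.77, adjusted p = 0.19) and Il12b (0.49, adjusted p = 0.219). Without rituximab replicate 2 and trastuzumab replicate 5, the tumours that stood apart, Cxcl9 (adjusted p = 0.0112), Cxcl10, Fcgr1 and Irf7 (each with an adjusted p = 0.00191) passed, as they did with array weights. Cxcl9 and Fcgr1 also passed without the lowest 25% of genes, with a pseudocount of 10 and with trend and robust settings, Cxcl10 with the last of these and Cxcl9 with edgeR. Of 30 interferon-stimulated genes, 27 had positive values and 0 passed (7 when adjusted over the list alone; median 0.48, adjusted p = 0.276). Rituximab replicate 2 stood apart from its group in the same genes, with Irf7 at 994 against 303 to 458 in the other 4 tumours and Isg15 at 568 against 173 to 230. This tumour was picked out after the data were seen and had the lowest array weight (0.489). Leaving it out or down-weighting it widens the difference of genes in which it is high. Those settings are therefore not independent support for such genes. Among 17 genes of the interferon gamma response and MHC class I, 2 rose, Gbp5 and Psmb10 (8 higher and 1 lower when adjusted over the list alone; median 0.35, adjusted p = 0.2 by fry). Fry passed 0 of 30 lists, with 5 at an unadjusted p under 0.05; camera with the preset correlation passed 3 upwards, interferon-stimulated genes (adjusted p = 7.70e-07), interferon gamma with MHC class I (adjusted p = 0.000174) and lymphocyte-attracting chemokines (adjusted p = 0.00942), and with an estimated one 0. The gene count rested on single tumours: it was 38 without rituximab replicate 2, including the 7 genes, 14 without rituximab conjugate replicate 3, 4 with median centring, and 3 or 4 without any of the other rituximab replicates or rituximab conjugate replicates 1, 4 or 5. Of the 7, Cxcl11 and Psmb10 passed under neither other scaling, Ccl12 not with median centring, and only Tnf and Ccl4 passed with the compared groups alone.

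The conjugates were then compared with each other, at the same dose and day. This comparison includes what each antibody does without the agonist, which the interaction below takes out. Il1rn, for example, was also higher after plain trastuzumab than after plain rituximab (1.84). The trastuzumab conjugate group had 109 genes higher and 17 lower than the rituximab conjugate group. Il1rn differed most (2267 ± 871 against 225 ± 93.6, SD, n = 5; 3.35, 95% interval 2.50 to 4.21, adjusted p = 3.29e-05). Cxcl11 (2.47), Cxcl9 (2.39), Il10 (2.07), Ccl5 (2.06) and Ccl4 (1.98) were higher too, and so was Ccl20 (2.09), at 30.9 ± 13 against 6.46 ± 3.81 (SD, n = 5). Of the monocyte-attracting chemokines, 9 of 11 were higher, Ccl2 by 1.39 (10 when adjusted over the list alone; median 0.92, adjusted p = 1.45e-05, and adjusted p = 0.243 with an estimated correlation). Of the Fc receptor list, 10 of 13 were higher, Fcgr4 by 0.97 (10 when adjusted over the list alone; adjusted p = 0.000946, and adjusted p = 0.338 with an estimated correlation). Of the NF-kB list, 8 of 12 were higher, Nfkb2 by 0.44 (9 when adjusted over the list alone; adjusted p = 5.39e-05, and adjusted p = 0.293 with an estimated correlation). Tnf did not pass (0.40, adjusted p = 0.254).

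Neutrophil genes were higher after the trastuzumab conjugate than after the rituximab conjugate. Of 13 neutrophil markers, 6 were higher (6 when adjusted over the list alone), including the alarmin subunit S100a8 (1.71; 808 ± 321 against 246 ± 89.4, SD, n = 5), the gelatinase Mmp9 (1.42), the chemokine receptor Cxcr2 (1.26) and the growth factor receptor Csf3r (0.87). The list had a median of 0.63 (adjusted p = 0.000415, and adjusted p = 0.338 with an estimated correlation). Of 6 neutrophil-attracting chemokines, 3 were higher, including Cxcl2 (1.52) and Cxcl1 (1.39), and 3 when adjusted over the list alone (median 1.00, adjusted p = 0.0223, and adjusted p = 0.442 with an estimated correlation). This chemokine list did not pass fry with median centring (adjusted p = 0.0729). Of 7 inflammasome genes, 3 were higher, including Il1b (1.70) and Nlrp3 (0.69), and 4 when adjusted over the list alone (adjusted p = 0.00051, and adjusted p = 0.338 with an estimated correlation). Of 17 proinflammatory cytokines, 6 were higher, among them Il1a (1.60), and 7 when adjusted over the list alone (adjusted p = 0.00111, and adjusted p = 0.359 with an estimated correlation). Plain trastuzumab had S100a8 at 749 ± 295 and Il1b at 509 ± 210 (SD, n = 5), and neither gene passed between the trastuzumab conjugate and trastuzumab (S100a8 0.14, adjusted p = 0.83).

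MHC class II genes were lower. Of 11 genes of MHC class II presentation, 5 were lower, including H2-Eb1 (-0.62), H2-Aa (-0.59) and the invariant chain Cd74 (-0.51), while the protease gene Ctsl was higher (1 higher and 6 lower when adjusted over the list alone). The list median was -0.49 (adjusted p = 0.0123, and adjusted p = 0.293 with an estimated correlation), and the list also passed downwards under both other scalings. With the compared groups alone H2-Eb1 (adjusted p = 0.0663 by limma), H2-Aa (0.0865), Cd74 (0.104) and Ctsl (0.139) did not pass. Cd74 also did not pass with array weights (0.0617). H2-Aa, Cd74 and Ctsl lost their calls in at least 1 fit that left out a tumour. The other lower genes included Cx3cr1 (-2.03), Ccl17 (-1.74), Gpr183 (-0.76), Cd33 (-0.75), Tlr9 (-0.74), Tlr7 (-0.67) and Rps6 (-0.60), whereas Tlr2 (0.64) and the lipopolysaccharide coreceptor Cd14 (1.08) were higher. Tlr7 did not pass by limma with array weights (adjusted p = 0.0607), the compared groups alone (0.145) or the replicate number as a block (0.0908). Tlr7, Gpr183 and Rps6 also lost their calls in at least 1 fit that left out a tumour.

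The groups did not overlap for 88 of the 770 genes, where chance gives 6.1, and 76 of these were among the 126. Of 30 lists, 15 passed fry, 14 upwards and 1 downwards (10 and 9 with median centring, 11 and 6 with quantile normalization, where the endothelial, fibroblast, death receptor and type I interferon lists fell under both); 7 passed camera with the preset correlation, 4 upwards and 3 downwards (MHC class II, endothelial markers, and fibroblast and matrix genes), and 0 with an estimated one. Centring on medians gave 97 genes (58 higher, 39 lower) and quantile normalization 119 (62 higher, 57 lower), with the median change of all genes moved by -0.18 and -0.153. Under all 3 scalings 74 genes (57 higher, 17 lower), 10 lists upwards and MHC class II downwards passed; Cxcr2, Nlrp3, Nfkb2 and Ctsl passed under neither other scaling.

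**Figure D2:**
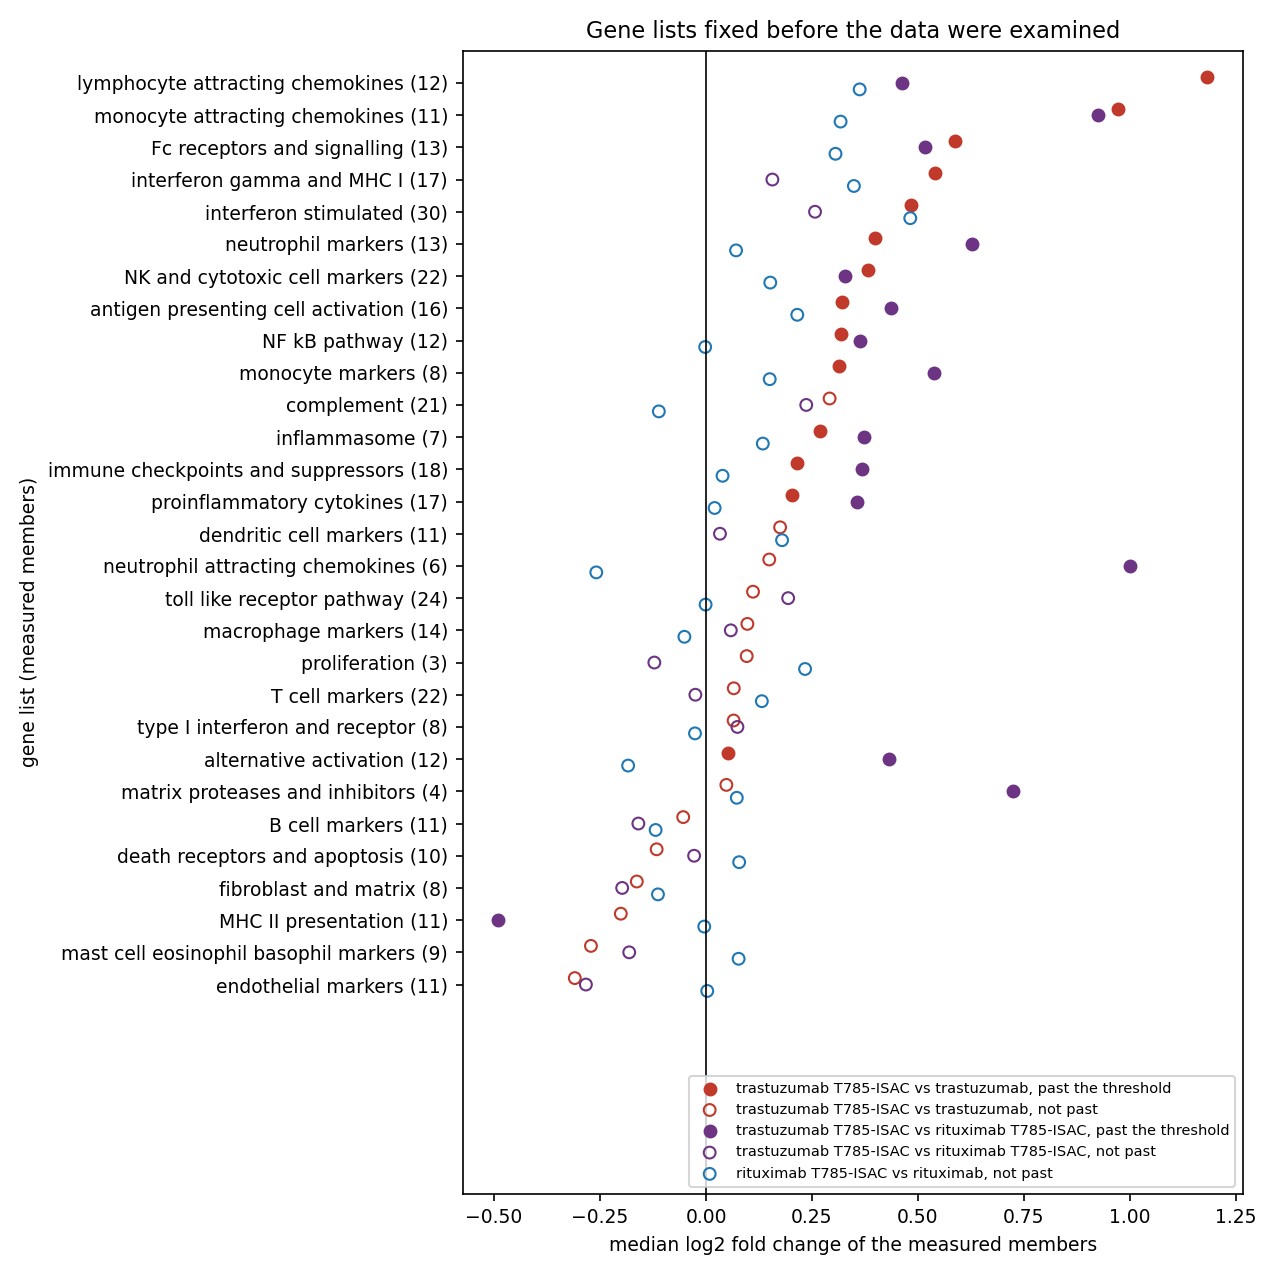
Median log2 fold change (horizontal axis) of the measured members of each gene list, with their number in brackets, in 3 comparisons; filled points passed fry at an adjusted p of 0.05 and open points did not, and the reference genes are left out. The trastuzumab conjugate against trastuzumab has 14 filled points, against the rituximab conjugate 15, and the rituximab conjugate against rituximab 0.

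The plain antibodies were compared to ask what trastuzumab does without the agonist. Il1rn (588 ± 260 against 141 ± 21.8, SD, n = 5; 1.84, 95% interval 0.99 to 2.69, adjusted p = 0.0478), Mmp9 (1.25), Ccrl2, an atypical receptor that binds chemerin (1.10), and Il2rg, the common cytokine receptor chain (0.56; these 3 with an adjusted p = 0.0301) were higher after trastuzumab than after rituximab, and 0 genes were lower. The groups did not overlap for 21 of the 770 genes, where chance gives 6.1, and these included Mmp9 and Il2rg but not Ccrl2 and Il1rn. S100a8 (1.31, adjusted p = 0.101), Il1b (1.26, adjusted p = 0.115), Cxcr2 (1.33, adjusted p = 0.115) and Nlrp3 (0.55, adjusted p = 0.251) did not pass. With array weights, and without both tumours that stood apart, S100a8 (adjusted p = 0.00787 and 0.0167), Il1b (0.00787 and 0.00493) and Cxcr2 (0.0126 and 0.019) did, as did S100a8 and Il1b with edgeR and the authors' factors (0.0305 and 0.0409) and S100a8 with trend and robust settings (0.0488). Of 30 lists, 3 passed fry upwards, each with an adjusted p = 0.0419 and an adjusted p = 0.441 with an estimated correlation. They were neutrophil markers (1 of 13 genes passed, 5 when adjusted over the list alone; median 0.24), inflammasome genes (0 of 7, 4 when adjusted over the list alone; median 0.55) and matrix proteases with their inhibitors (1 of 4, 1 when adjusted over the list alone; median 0.55).

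Trastuzumab replicate 5 stood apart from its group in these genes, with Il1rn at 133 against 642 to 772 in the other 4 tumours, Il1b at 148 against 502 to 657, and S100a8 at 324 against 638 to 1128. This tumour was picked out after the data were seen, and its array weight was 0.517. Leaving it out or down-weighting it widens the difference of genes in which it is low, so neither is independent support for them. Without it 23 genes passed, the 4 among them, and 6 lists. Without any 1 of the other 9 tumours 0 genes passed, and 0 lists without any 1 of rituximab replicates 1, 3 and 4 or trastuzumab replicates 1 to 4. Centring on medians also left 0 genes and 0 lists, with limma finding 95 at an unadjusted p under 0.05 on the deposited scale and edgeR 4 to 8 at the adjusted threshold; Il1rn and Il2rg did not pass with quantile normalization.

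Finally, the interaction tested whether the change with conjugation differed between the antibodies. The change under trastuzumab minus that under rituximab was above 0 for 9 genes and below 0 for Cx3cr1; for Arg2, Ifitm1, Ifitm2, Fcgr2b and Cd38 the value was positive under trastuzumab and negative under rituximab. Ccl5 (1.59, 95% interval 0.99 to 2.19, adjusted p = 0.00803) and Fcgr4 (1.32, 95% interval 0.81 to 1.82, adjusted p = 0.00803) had the lowest p of the 9, followed by Cd38, an NAD-consuming ectoenzyme (1.02, adjusted p = 0.00976). Il10 differed by 2.06 (adjusted p = 0.0271): it was 77.01 ± 30.03 against 12.4 ± 3.48 with and without the agonist on trastuzumab, and 16.4 ± 3.42 against 13.1 ± 5.39 on rituximab (SD, n = 5). The others were Ccl3 (1.35, adjusted p = 0.0333), Arg2 (1.33, adjusted p = 0.0271), Ifitm1 (1.30, adjusted p = 0.0196), Ifitm2 (0.69, adjusted p = 0.0246) and Fcgr2b (1.10, adjusted p = 0.0275). Arg2, a mitochondrial arginase, was 148 ± 41.6 after the trastuzumab conjugate, 94.0 ± 7.51 after trastuzumab, 56.2 ± 14.1 after the rituximab conjugate and 93.7 ± 26.6 after rituximab (SD, n = 5). Cx3cr1 had an interaction of -2.05 (95% interval -2.59 to -1.51, adjusted p = 0.000165).

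The monocyte-attracting chemokines had an interaction above 0 (2 of 11 passed, 9 when adjusted over the list alone; median 0.87, adjusted p = 0.00694, and adjusted p = 0.34 with an estimated correlation). So did the NF-kB list (0 of 12 passed, 4 when adjusted over the list alone; median 0.27, adjusted p = 0.0152, and adjusted p = 0.54 with an estimated correlation), which no longer passed under either other scaling; MHC class II passed downwards with quantile normalization (median -0.42, adjusted p = 0.00671). Fcgr2b and Ifitm2 did not pass with quantile normalization, nor Il10, Ccl3 and Ifitm1 without both tumours that stood apart. Leaving out 1 tumour at a time gave 4 to 17 genes: 4 without rituximab replicate 5, 5 or 6 without rituximab replicate 4, rituximab conjugate replicates 4 or 5, trastuzumab replicates 2 or 3 or trastuzumab conjugate replicate 2, and 16 or 17 without rituximab replicate 3, rituximab conjugate replicate 3 or trastuzumab conjugate replicate 1.

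**Figure D3:**
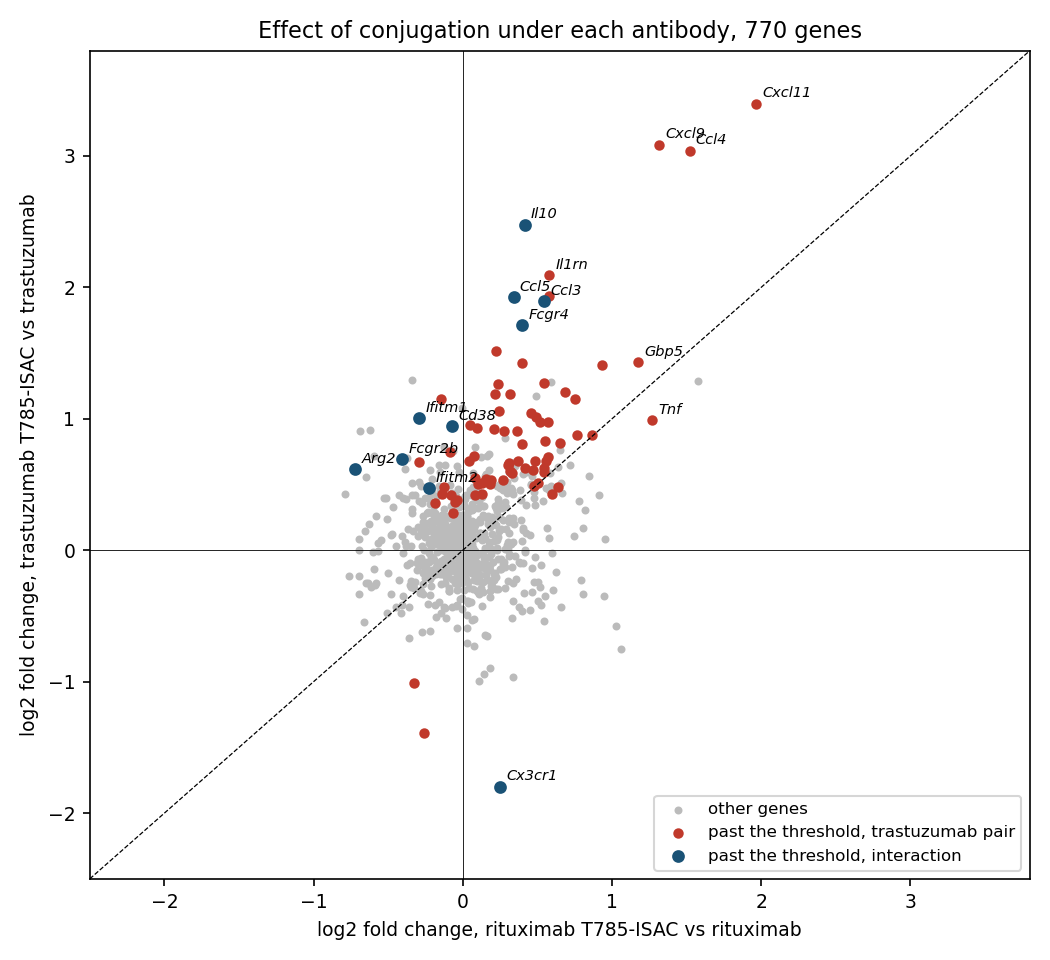
Log2 fold change with conjugation for each of 770 genes under rituximab (horizontal axis) and trastuzumab (vertical axis); red points passed in the trastuzumab pair, blue points passed the interaction test, grey points are the other genes and the dashed line marks equal change. Il10, Ccl5, Ccl3 and Fcgr4 lie above the line, Cx3cr1 lies below it, and Tnf has 0.99 under trastuzumab and 1.27 under rituximab.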

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

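The tests of macrophage markers and of a sample swap were chosen only after the result was seen, as were the spread allowed in the test outside the interferon lists and the comparison of the epithelial genes with all 770 genes.

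Among 75 genes named above, 16 of 300 groups of 5 tumours held 1 tumour far from the other 4 (a gap above 0.71 of the range), where chance gives about 1 in 20 groups, or 15. Of these, 8 were in trastuzumab replicate 5 and 3 in rituximab replicate 2. In trastuzumab replicate 5 the values were 37.4 for Cxcl9 (others 61.9 to 72.0), 132.5 for Il1rn (641.9 to 772.4), 95.1 for Cxcl10 (195.2 to 231.9), 148.1 for Il1b (502.2 to 656.6), 187.9 for Csf3r (251.1 to 273), 332.1 for Cd14 (515 to 586.4), 42.9 for Ccrl2 (80.9 to 103.5) and 124 for Il2rg (163 to 174.4). In rituximab replicate 2 they were 708.6 for Psmb8 (476.9 to 534), 869.2 for Zbp1 (293.7 to 387.9) and 45.9 for Ccr7 (66.8 to 74.9). In rituximab conjugate replicate 3 Fcgr4 was 742.3 (535.8 to 579.9) and Emr1 3352.3 (1399 to 1664.5), and in replicate 5 Ncr1 was 110 (61.3 to 68.2). In trastuzumab conjugate replicate 1 Csf3r was 233.5 (317.9 to 343.8). Lyn in trastuzumab replicate 1 was 360.6 (292.4 to 308.9).

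The change with conjugation differed between trastuzumab and rituximab, by limma's interaction test, for Il10 (2.06), Ccl5 (1.59), Ccl3 (1.35), Arg2 (1.33), Fcgr4 (1.32), Ifitm1 (1.30), Fcgr2b (1.10), Cd38 (1.02), Ifitm2 (0.69) and Cx3cr1 (-2.05), all on the log2 scale.

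The fall of Cx3cr1 after the trastuzumab conjugate is the pattern that runs against most of the panel. Cd33, a myeloid receptor outside the lists of macrophage and monocyte markers, fell too (-1.01). The other 21 measured markers in those lists did not share the fall. Their median change was 0.148 (median absolute deviation 0.464), above -0.899, which is 50% of the change of Cx3cr1, and the lowest was -0.241. This argues against a matching loss of all these cells only if their markers did not rise per cell. Some markers rose after the conjugate, such as Fcgr4 (1.71) and Fcgr1 (0.97), so the median does not measure cell number. The authors' scaling is argued against by changes of -1.98 with median centring and -1.965 with quantile normalization, and depth by a change of -1.893 after every tumour was thinned to 359848 counts. Loss of a Cx3cr1-high subset of these cells, or less transcript per cell, may underlie it; neither was tested here.

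Rituximab replicate 2 stood apart with interferon-induced genes, such as Ifit2 at 957 (others 249 to 438), and with epithelial genes, such as Epcam at 60.1 (4.45 to 5.64) and Cdh1 at 136 (18.1 to 25.4). Genes that a piece of skin could raise were also high: Ccl27a at 102.64 (6.68 to 12.11), Cd207 at 32.76 (5.64 to 8.9) and Defb1 at 22.93 (1.11 to 3.82). All these genes were picked for their large differences in this tumour, so they cannot decide whether skin was present. A piece of skin could not be told apart from other causes: the tumour was the highest of its group for 5 of 8 epithelial genes listed without looking at their values, but it was so for 239 of all 770 genes (31%), which gives as many with a chance of 0.0664; the bound set in advance had assumed 1 in 5. A conjugate-treated mouse under this label would be consistent with its position of 0.736 between the other rituximab tumours (0; -0.187 to 0.249) and the rituximab conjugate tumours (1; 0.695 to 1.233). Over the 63 genes outside the interferon lists the position was 0.605, below the lowest conjugate tumour (0.693) by less than their SD of 0.252, which decides nothing. A swap with a rituximab conjugate tumour is argued against by position alone, since the lowest of these, each placed on an axis built without it, lay at 0.695. Rituximab conjugate replicate 3 lay at 0.703, although exchanging it with this tumour gave 36 genes against 7 with the labels as deposited. An unequal interferon response of this mouse stays open and untested.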

How the results depend on the processing

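The edgeR tests, the removal of both tumours that stood apart (rituximab replicate 2 and trastuzumab replicate 5) and the removal of Cd3eap are tests chosen only after the results were seen. Gene counts of the trastuzumab conjugate against trastuzumab (79) and against the rituximab conjugate (126) stayed within 1.5 times under each of 12 alternatives, at 73 to 109 and 90 to 136. The rituximab pair (7 genes) gave 4 with median centring, 16 without the lowest 25% of genes, 15 with a pseudocount of 10, 17 with trend and robust settings, 31 with array weights, 2 with the compared groups alone, 39 without both tumours and 12 with edgeR and the authors' factors. The plain antibodies (4 genes) gave, for the settings in question, 0 with median centring, 2 with quantile normalization, 38 with array weights, 0 with the compared groups alone, 24 without both tumours and 8 with edgeR and the authors' factors. The interaction (10 genes) gave 16 without the lowest 25%, 22 with a pseudocount of 10, 19 with trend and robust settings and 27 with array weights, and its split went from 9 higher and 1 lower to 7 and 3 with quantile normalization (lists from 2 upwards to 1 upwards and 1 downwards). With edgeR and TMM the splits were 59 higher and 14 lower for the trastuzumab pair and 77 and 28 for the conjugates. Fewer genes tested or fewer tumours are part of some settings; otherwise the cause was not tested. Array weights were lowest for rituximab replicate 2 (0.489) and trastuzumab replicate 5 (0.517).

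Camera with an estimated correlation passed 0 lists in every comparison, against 14 by fry for the trastuzumab pair, 15 for the conjugates, 3 for the plain antibodies and 2 for the interaction. With the preset correlation it passed 3 for the rituximab pair, 7 for the conjugates (4 upwards, 3 downwards) and 5 for the interaction (3 upwards, 2 downwards). Median centring left 0 lists for the plain antibodies and 1 for the interaction. Without both tumours 3 lists passed for the rituximab pair, 5 for the plain antibodies and 1 for the interaction. Lists that fell in the trastuzumab pair under both other scalings, but not as deposited, were MHC class II, death receptors, type I interferon with its receptors, and the reference genes. Rescaling by the reference genes moved no tumour by more than 7e-04 and says nothing about stability. Without Cd3eap, an RNA polymerase I subunit, the T cell list had 21 members and an adjusted p = 0.988 for the trastuzumab pair.

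The replicate number as a block gave 74, 4, 104, 0 and 8 genes and 15, 0, 13, 0 and 2 lists in the order of the comparisons. The numbers do not pair the tumours: residual correlations of equal numbers were -0.268 to 0.219, and 0 of 20 tumours correlated best with their own number.

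Leaving out 1 tumour at a time gave 63 to 90 genes and 9 to 16 lists for the trastuzumab pair (9 lists without trastuzumab replicate 3 or trastuzumab conjugate replicate 2). It gave 3 to 38 genes and 0 to 3 lists for the rituximab pair (38 genes and 3 lists without rituximab replicate 2), and 84 to 130 genes and 12 to 18 lists for the conjugates. For the plain antibodies it gave 0 to 23 genes and 0 to 6 lists (23 and 6 without trastuzumab replicate 5), and for the interaction 4 to 17 genes and 2 to 6 lists (6 without trastuzumab conjugate replicate 1). Of the named genes that passed, 38 of 43, 3 of 7, 23 of 32, 0 of 4 and 4 of 10 passed in every such fit.

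For named genes, 1228 of 1355 values under the other alternatives kept direction and side of the threshold, 89 no longer passed, 31 came to pass (Cxcl10 in the trastuzumab pair; Cxcl9, Cxcl10, Fcgr1 and Irf7 in the rituximab pair; S100a8, Il1b and Cxcr2 with the plain antibodies) and 7 changed sign. Those were of Emr1 and S100a8 in the trastuzumab pair, which never passed: Emr1 -0.144 with median centring, -0.131 with quantile normalization and -0.08 with edgeR and TMM; S100a8 -0.047, -0.072 and -0.01 for the same, and -0.134 without both tumours. Leaving out 1 tumour, Emr1 ranged from -0.063 to 0.11 and S100a8 from -0.134 to 0.314: Emr1 was -0.047 without trastuzumab replicate 2 and -0.063 without trastuzumab conjugate replicate 5, and S100a8 -0.134 without trastuzumab replicate 5 and -0.057 without trastuzumab conjugate replicate 3. Depth limits genes near 3 counts, such as Ccl17.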

Other observations

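The test of the lopsided split and that of the higher genes under other scalings were chosen only after the result was seen.

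Several lists of markers of other cell types did not pass fry between the trastuzumab conjugate and trastuzumab. The T cell list (22 members, median 0.07, adjusted p = 0.934) and the B cell list (11 members, median -0.05, adjusted p = 0.96) did not pass fry. The mean levels of Cd3e and Ms4a1 were 2.3 to 4.5 in the 4 groups, near the limit of 3 counts, in mice that lack mature T and B cells. Endothelial markers (11 members, median -0.31, adjusted p = 0.205), fibroblast and matrix genes (8 members, median -0.16, adjusted p = 0.0968) and markers of mast cells, eosinophils and basophils (9 members, median -0.27, adjusted p = 0.205) had medians below 0 and did not pass fry on the deposited scale. On that scale camera with the preset correlation passed the endothelial markers (adjusted p = 0.0116) and the fibroblast and matrix genes (adjusted p = 0.0273) downwards. By fry the fibroblast and matrix genes and the markers of mast cells, eosinophils and basophils passed downwards with median centring. The endothelial markers passed downwards by fry with quantile normalization. Of the dendritic cell markers, Ccr7 rose and Ccl17 fell (11 members, adjusted p = 0.0586), although Ccl17 did not pass with a pseudocount of 10 or with edgeR. The type I interferon gene Ifnb1 had mean values of 2.2 to 3.8, around the limit of 3 counts, and did not pass (-0.54, adjusted p = 0.214).

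Other lists that did not pass fry in this comparison were complement (median 0.29, adjusted p = 0.161), toll-like receptor pathway (0.11, 0.178), macrophage markers (0.10, 0.178), neutrophil-attracting chemokines (0.15, 0.754), type I interferon with its receptors (0.07, 0.394), death receptors (-0.12, 0.981), proliferation (0.10, 0.777), matrix proteases (0.05, 0.53), MHC class II (-0.20, 0.0988; downwards by camera with the preset correlation, adjusted p = 0.0116) and the reference genes, whose mean the scaling fixes (adjusted p = 0.157). Passing upwards, beside the lists described above, were checkpoints and suppressors (3 of 18 genes, 6 higher and 1 lower when adjusted over the list alone, median 0.22, adjusted p = 0.0026), among them Socs3, an inhibitor of cytokine signalling (0.95), neutrophil markers (1 of 13, the formyl peptide receptor Fpr2 at 1.41; median 0.40, adjusted p = 0.0294) and inflammasome genes (0 of 7, median 0.27, adjusted p = 0.0294). With an estimated correlation their adjusted p was 0.512, 0.716 and 0.648. Keratinocyte, platelet and hypoxia lists had too few measured members for a test.

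Across genes, which are not independent replicates, the changes with conjugation under trastuzumab and under rituximab had a Pearson correlation of 0.35 and a Spearman correlation of 0.203, and 64 of the 79 genes that passed under trastuzumab had the same sign under rituximab.

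Most genes that passed in the trastuzumab pair were higher (76 of 79, 96.2%). A difference in depth is argued against: after every tumour was thinned to 359848 counts, 74 of the 79 genes still passed in the same direction. Of the 76 higher genes, 46 still passed as higher with median centring and 40 with quantile normalization. The authors' scaling is argued against as the cause of the calls only for the 40 that passed under all 3 scalings. The other calls depended on the scaling. The scaling cannot be told apart from a rise of much of an immune panel as the cause of the lopsided split. The share of higher genes was 59.7% with median centring and 51.9% with quantile normalization, and either would give such a fall. A rise of much of the panel remains a hypothesis that may be tested with spiked controls.

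For each count, the tumours compared were also split into other groups of the same sizes, with 100 splits drawn, the real one included. Chance is excluded for genes of the trastuzumab pair (79; highest other split 16; 1 split with as many) and of the conjugates (126; 54; 1). The rituximab pair (7; 36; 3) lies under the 5% bound on the splits drawn, by too few splits to exclude chance firmly. For the interaction (10; 30; 2) the splits mixed all 20 tumours over the 4 groups. This also removed the differences between antibodies and with conjugation, so these splits cannot decide whether the interaction itself is due to chance. It is not excluded for the plain antibodies (4; 17; 5). For lists chance is excluded, on the splits drawn, in the trastuzumab pair (14; 10; 1). The conjugates (15; 14; 1), where another split gave nearly as many lists, and the plain antibodies (3; 8; 2) lie under the bound but not firmly. Chance is not excluded for lists in the rituximab pair (0; 3; 100). Nor is it for lists in the interaction (2; 10; 5), where the splits mixed the groups in the same way. Splits with several times the real count of genes, as in the rituximab pair and the plain antibodies, point to a structure of the samples. The split with 30 genes in the interaction mixed the 4 groups, so it shows no such structure apart from the treatments. In the rituximab pair the splits with 36 and 25 genes put rituximab replicate 2 with conjugate tumours, the first by exchanging it with rituximab conjugate replicate 3, and in the plain antibodies the splits with 17, 13, 12 and 11 genes put trastuzumab replicate 5 with the rituximab tumours.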
